A study of Pinctada imbricata with 12 samples.

How the data were processed

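Total RNA of 12 samples was labelled with Cy3 and hybridized to one-colour Agilent arrays, per the labels' protocols. There were 4 groups of 3 samples, taken from the tissue and replicate number in the labels. The scanner output of each array holds intensity values per spot that the authors made with Agilent Feature Extraction 10.7, per the submitters' processing notes. The processed signal of a spot is background-corrected by that software, per the file headers. The deposited value table of the series is on a log2 scale. Set against the scanner values, each of its columns followed its own array best (lowest r = 0.998), all medians were 6.931, and sorted columns differed by at most 0.008, so the columns share 1 distribution, as after quantile normalization. The software behind that table is not given in the sources used here, and it served only as an alternative.

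Of 45220 spots, 43803 were not controls. They covered 30123 probes with 29821 distinct sequences, and 1368 probes had 11 spots each, which were averaged in log2. Control spots and 334 to 487 spots per array marked as outliers were left out, and no spot was saturated. The median SD of repeat spots was 0.051 to 0.077 log2. The main values are log2 of the processed signal minus the array's 75th percentile, which lay between 465 and 947 signal units. A probe was tested if it was well above background on all 3 arrays of at least 1 group, which left 22008 probes. The 6 pairs of groups were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, in 1 fit over all 12 arrays without further terms. A probe was called at a Benjamini-Hochberg adjusted p below 0.05 and at least a 2-fold difference. A probe entered a class if it was called in the same direction in every comparison of the class. Where a probe was not well above background on any array of the lower group, the fold is written as at least N-fold. That bound sets the mean of the higher group against the mean, per array, of the probe's own level or the lowest level among probes well above background, whichever was higher.

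The array files pair probes with no gene name, and no reference for this species was used here. The gene lists fixed beforehand could therefore not be matched to probes and the tests of list shifts were not run. By the rule fixed before the data were examined, at most 2 probes with the highest and 2 with the lowest difference were named per comparison and 2 per class. A named probe had an adjusted p below 0.05 and all 3 arrays of the higher group above all 3 of the lower. The 5 classes, all comparisons and most alternatives were also fixed before the data were examined.

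Whether the replicate numbers pair the samples was checked from the deviations of each array from its group mean. Same-numbered arrays of different tissues correlated at 0.31 to 0.78 in all 18 pairs. The 9 pairs without gonad lay at 0.55 to 0.78 and the 9 with a gonad pool at 0.31 to 0.51. Differently numbered arrays of different tissues correlated at -0.461 to -0.014. Negative values there follow from the positive ones, since deviations from a group mean cancel out, and are no separate evidence. The design text says that the other tissues came from 3 individuals, and the numbers share the labelled sex, so the numbers were taken to pair the samples. Each slide held exactly the arrays of 1 number, so slide and animal cannot be told apart by a block. Each slide holds 1 array per group, so the difference between tissues within a slide has a value but no test, and the block uses these differences over the 3 slides. The p-values measure the spread between these samples. The fits were tested on simulated data for the comparison of mantle edge with mantle centre over 21888 probes. Without the block, 0%, 24%, 70% and 96% of probes changed by 1, 2, 4 and 6 log2 were called, with 1 false call. With the replicate number as a block these shares were 0%, 48%, 90% and 98%, with 9 false calls.

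Alternatives were quantile normalization, median centring, normexp background correction with an offset of 50 on the mean and local background signals, no filter on dim probes, only probes well above background on all 12 arrays, the deposited value table, the replicate number as a block, a fit of the compared groups alone, an intensity trend with robust moderation, other minimum folds, and leaving out each array in turn. Counting identical sequences once, leaving out probes that set the mantle and viscera arrays of 1 replicate number apart, and leaving out the 4 arrays numbered 2 were added after seeing the data. All possible splits of 6 arrays (10) and 100 relabellings of the 12 arrays were refitted. Amino-acid content was read from the 3 forward frames of each probe with Biopython 1.88, and tested with Fisher's exact test in scipy 1.17.1. Similar probes were found with BLAST 2.17.0.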

Results

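Gene expression was measured in 4 tissues of the pearl oyster Pinctada fucata martensii, a bivalve whose mantle secretes the shell. The tissues were the mantle edge, the mantle centre, the gonad and a composite of visceral organs made of gill, foot, heart, intestine, hepatopancreas and adductor muscle. The mantle edge of pearl oysters lays down the outer, prismatic part of the shell, and the more central mantle lays down nacre. The series title names candidate biomineralization genes as its subject, so the comparisons asked which probes separated the shell-forming mantle from the other tissues and the edge from the centre. Each tissue was hybridized to 3 one-colour arrays, giving 12 arrays on 3 slides, and each slide held 1 array of every tissue. The mantle and viscera samples numbered 1 and 3 were labelled female and those numbered 2 male, and each gonad sample pooled a male and a female. Each array carried 30123 distinct probes of 60 bases, and between 66.4% and 72.8% of them were well above background on any array. With 3 arrays per tissue, their number limits the precision of every value. The array files pair no probe with a gene name, so probes are identified by their design name and sequence, and no gene function is given.

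The tissues separated into 3 sets of arrays. The first principal component, with 53.6% of the variance over 21888 probes, parted the 6 mantle arrays from the gonad arrays, and the second, with 17.0%, parted the viscera from the rest. Arrays of mantle edge correlated with each other at 0.891 to 0.897 across probes, which are not independent replicates. Edge and centre arrays correlated at 0.773 to 0.906, whereas edge and gonad arrays reached only 0.396 to 0.471. Gonad and viscera arrays lay between these at 0.591 to 0.743. The 3 mantle centre arrays correlated with each other at 0.859 to 0.873. Within a slide, which held 1 array per tissue and so allowed no test, the probes called in each comparison below mostly kept their direction by at least 2-fold. These shares, over probes chosen on the same arrays, were 98.5% to 99.8% for edge against centre and 89.2% to 99.8% over all 6 comparisons and 3 slides.

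**Figure D1:**
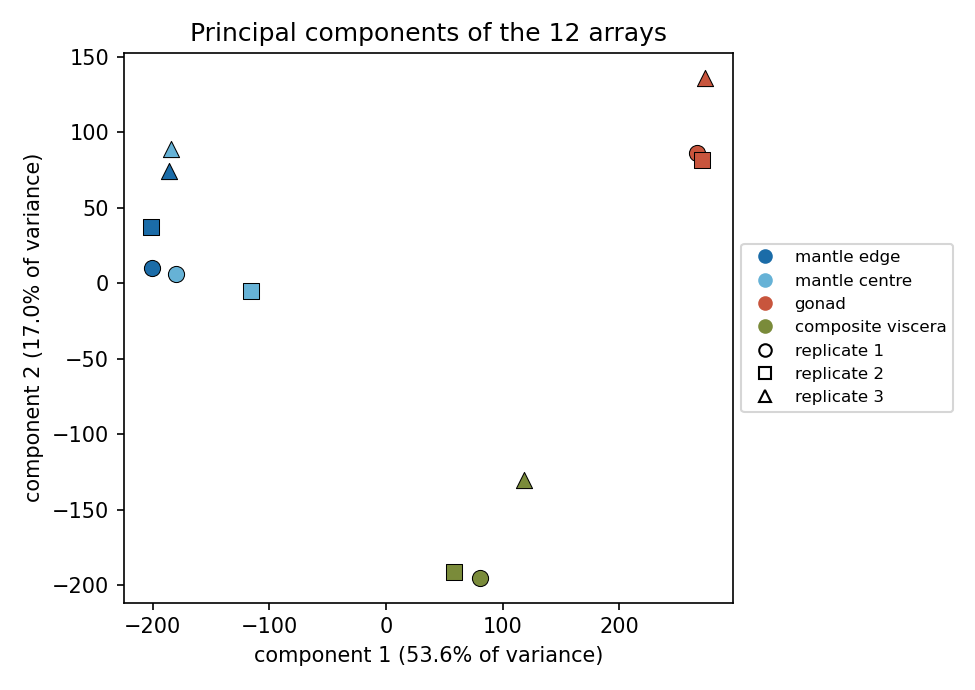
Scores of the 12 arrays on the first principal component (horizontal axis, 53.6% of the variance) and the second (vertical axis, 17.0%), with colour for the tissue and symbol shape for the replicate number. The mantle arrays lie on the left, the gonad arrays at the upper right and the viscera arrays at the bottom, and mantle centre replicate 2 lies nearest to the centre of the plot among the mantle arrays.

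The comparison of mantle edge with mantle centre asked which probes differed between the parts of the mantle that face different shell layers. In all, 606 of 22008 tested probes differed, of which 373 were higher in the edge and 233 higher in the centre. The excess in the edge depended on the processing, since normexp background correction gave 162 and 155, and leaving out the 4 arrays numbered 2, an alternative added after seeing the data, gave 160 and 179. The differences called were large, but the calls favour large ones. In the simulated data without the block, 24% of probes changed by 2 log2 were called, against 96% of those changed by 6. The median log2 fold among the edge-higher probes was 5.75, and among the centre-higher probes it was -7.63. Of the edge-higher probes, 23.1% were not well above background on any mantle centre array, and of the centre-higher probes 41.6% were not well above background on any mantle edge array. The probe with the highest edge over centre difference was CUST_26107_PI428626668 (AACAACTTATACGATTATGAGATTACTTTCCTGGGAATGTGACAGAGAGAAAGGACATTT), with a log2 fold of 10.75 ± 2.24 (SE, n = 3 per tissue, limma adjusted p = 0.0301). Its mantle centre arrays were far apart, at a mean of -3.90 ± 5.93 (SD, n = 3) relative to the array's 75th percentile, and it was well above background on 1 of them. CUST_2331_PI428626668 (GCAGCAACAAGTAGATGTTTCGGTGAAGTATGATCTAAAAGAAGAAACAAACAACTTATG) followed, at least 454-fold higher in the edge (limma adjusted p = 0.0138), with a spread of 5.25 log2 (SD, n = 3) over the edge arrays. The bound for CUST_2331 concerns the mean of its edge arrays, not each array. Which of these probes differed more is not settled, since CUST_2331 has only a lower bound. CUST_26107 lost the call of edge over centre without any 1 of the mantle edge or gonad arrays, mantle centre replicate 1 or 2 or viscera replicate 2, and also without all arrays numbered 2 or when only the compared tissues were fitted. CUST_2331 lost it without mantle edge replicate 1 or 2 or mantle centre replicate 2 or 3, without all arrays numbered 2, after normexp correction, and when only the compared tissues were fitted. In the other direction, CUST_5970_PI428626668 (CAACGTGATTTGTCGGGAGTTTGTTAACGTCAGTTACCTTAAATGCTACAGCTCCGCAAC) was at least 1377-fold higher in the centre (limma adjusted p = 2.59e-07), where its level was 4.99 ± 0.74 log2 (SD, n = 3). CUST_4475_PI428626668 (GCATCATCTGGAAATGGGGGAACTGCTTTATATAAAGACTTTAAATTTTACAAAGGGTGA) differed by a log2 fold of -11.63 ± 0.71 (SE, n = 3 per tissue, limma adjusted p = 5.54e-06), with 2 of 3 edge arrays well above background. The count fell to 317 probes after normexp background correction, to 47 among probes well above background on all 12 arrays, and to 339 without the 4 arrays numbered 2. With the replicate number as a block it rose to 786, of which 489 were higher in the edge and 297 in the centre. When only the compared tissues were fitted, 242 probes were higher in the edge.

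Of the 606 probes, 304 were higher in the mantle edge than in every other tissue and form the edge enriched class. Their median level was 1.90 ± 0.21 log2 in the edge (SD over array medians, n = 3), -4.49 ± 0.90 in the centre, -7.89 ± 0.16 in the gonad and -7.11 ± 0.33 in the viscera. A further 204 probes were higher in the mantle centre than in every other tissue. The median level of these centre enriched probes was 2.73 ± 0.36 log2 in the centre and -5.80 ± 0.49 in the edge, and in gonad and viscera it was -7.93 ± 0.39 and -7.54 ± 0.38. In the gonad, 63.2% of the edge enriched and 71.1% of the centre enriched probes were not well above background on any array. CUST_26107 and CUST_2331 led the edge class, although both also lost the call of edge over viscera without the arrays numbered 2, and CUST_2331 after normexp correction, and CUST_5970 and CUST_4475 led the centre class. The edge class fell to 140 probes after normexp correction, and among probes well above background on all 12 arrays the classes held 16 and 4 probes. Without the arrays numbered 2, the edge class held 144 probes.

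The comparison of both mantle parts with both other tissues asked which probes the whole mantle shared. There were 863 mantle shared probes, higher in edge and in centre than in gonad and than in viscera. Their median level was 2.17 ± 0.39 log2 in the edge (SD over array medians, n = 3), -7.46 ± 0.49 in the gonad and -6.96 ± 0.26 in the viscera. In the mantle centre the arrays lay apart, at 1.83 and 2.17 log2 on replicates 1 and 3 and -0.32 on replicate 2, a mean of 1.23 ± 1.35. Of the 863 probes, 75 were also edge enriched, 42 were also centre enriched and 746 were not called between edge and centre. The class was led by CUST_11723_PI428626668 (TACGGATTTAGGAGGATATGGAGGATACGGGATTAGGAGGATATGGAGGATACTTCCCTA), at 8.80 ± 0.36 log2 in the edge and 8.28 ± 1.94 in the centre (SD, n = 3 each), and by CUST_66_PI428626668 (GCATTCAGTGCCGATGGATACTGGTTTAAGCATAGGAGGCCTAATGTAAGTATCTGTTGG). Edge and centre were compared with the same gonad and viscera arrays. Of 22008 tested probes, 1320 in the edge and 1163 in the centre exceeded gonad and viscera. Independent lists would share 69.8, but these lists are not independent, since they rest on the same gonad and viscera arrays. In 20 simulated sets with unchanged groups every comparison gave 0 calls, so their overlap of 0 was fixed and sets no expectation. Part of the excess may come from the shared arrays, since 3 arrays per tissue cannot be divided into sets of at least 2 each. The class held 391 probes after normexp correction and 78 among probes well above background on all 12 arrays.

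**Figure D2:**
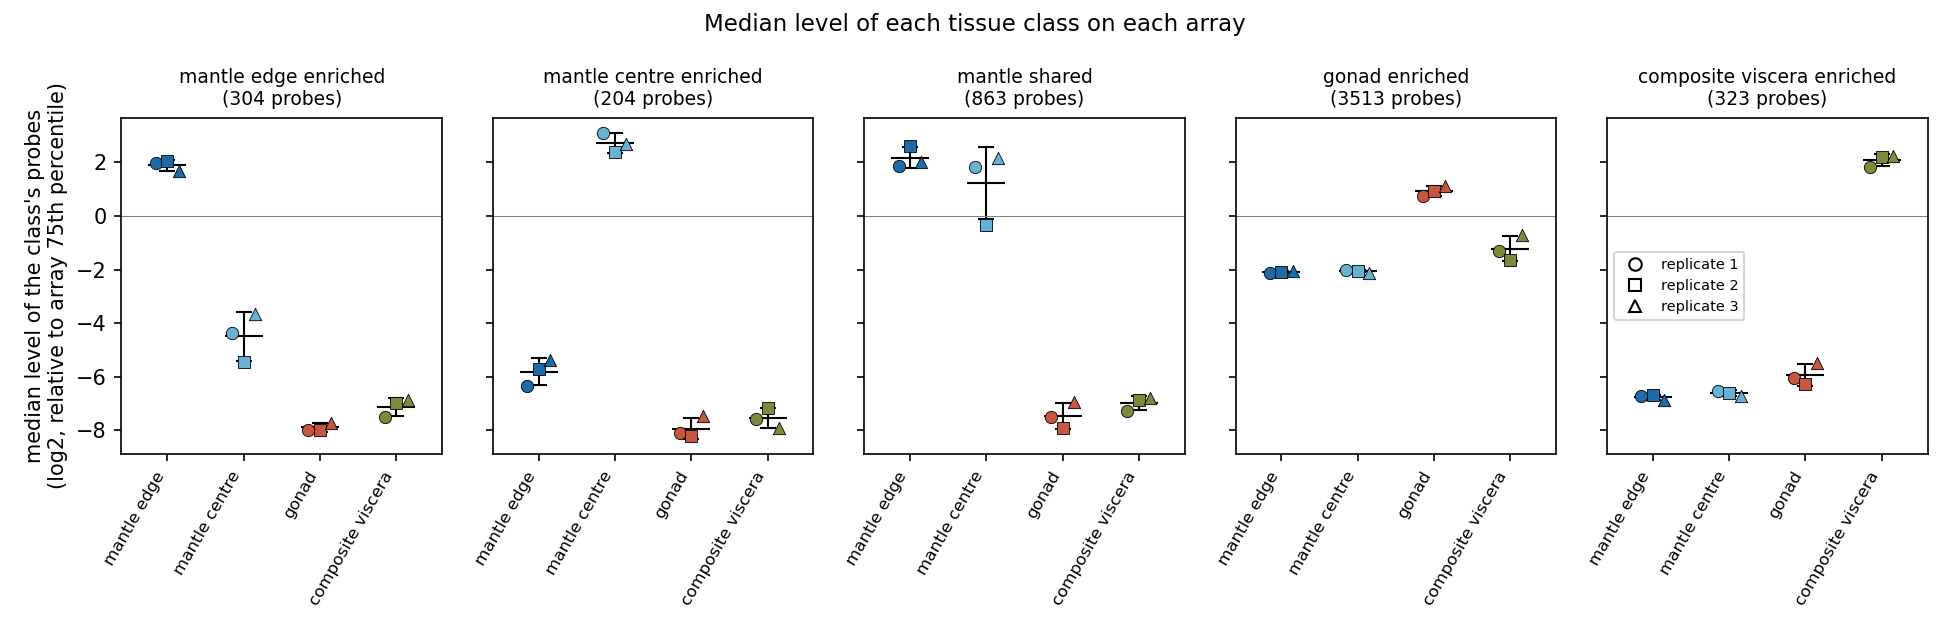
Median level of the probes of each class on each of the 12 arrays, in log2 relative to the array's 75th percentile. Symbols stand for arrays with their replicate number, and horizontal bars with whiskers stand for the mean and SD of 3 arrays. Mantle centre replicate 2 lies at -0.32 for the mantle shared probes, below 1.83 and 2.17 on the other centre arrays.

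Mantle edge and gonad differed at 11285 probes, with 6089 higher in the edge and 5196 higher in the gonad. Of these, 2034 differed by more than 32-fold, 1442 of them higher in the edge. CUST_122_PI428626668 (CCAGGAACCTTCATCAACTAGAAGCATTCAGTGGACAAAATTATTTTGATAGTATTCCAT) was at least 22465-fold higher in the edge (limma adjusted p = 4.34e-06). CUST_227_PI428626668 (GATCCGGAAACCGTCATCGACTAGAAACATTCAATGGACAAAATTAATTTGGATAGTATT) was at least 21334-fold higher (limma adjusted p = 5.14e-06), and neither was well above background on any gonad array. In the gonad, CUST_14087_PI428626668 (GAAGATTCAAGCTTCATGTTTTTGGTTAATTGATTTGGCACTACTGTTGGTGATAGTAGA) stood highest over the edge, at a log2 fold of edge over gonad of -12.64 with an SE of 2.32 and an adjusted p of 0.00116 from limma. It was well above background on 1 of 3 edge arrays, which spread by 2.01 log2 (SD, n = 3), so this fold rests mostly on background readings in the edge. CUST_15522_PI428626668 (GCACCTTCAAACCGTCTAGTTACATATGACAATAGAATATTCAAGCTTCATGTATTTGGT) followed, with a log2 fold of edge over gonad of -12.62 and an SE of 2.32, and was well above background on 2 of 3 edge arrays. Both SEs come from the fit over all 12 arrays, so they include the spread in tissues outside this comparison. Over the viscera arrays, CUST_14087 stood at 1.99 ± 5.96 log2 and CUST_15522 at 2.22 ± 5.90 (SD, n = 3 each). Their SDs were 0.27 and 0.13 log2 over the gonad arrays, and 2.01 and 2.10 over the edge arrays. Both SEs, and the adjusted p of CUST_14087, therefore reflect mostly the viscera arrays. The count was 7358 after normexp correction. The direction of the majority depended on the processing, since 54.0% of the calls were higher in the edge in the main fit, but 42.6% after median centring, 46.3% after quantile normalization and in the deposited value table, 43.8% after normexp correction and 49.7% among probes well above background on all 12 arrays.

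Mantle centre and gonad differed at 11279 probes, with 6281 higher in the centre and 4998 higher in the gonad. CUST_17850_PI428626668 (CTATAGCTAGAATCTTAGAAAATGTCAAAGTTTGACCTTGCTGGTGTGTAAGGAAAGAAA) was at least 32923-fold higher in the centre (limma adjusted p = 5.78e-08), at a level of 8.73 ± 0.06 log2 (SD, n = 3). CUST_466_PI428626668 (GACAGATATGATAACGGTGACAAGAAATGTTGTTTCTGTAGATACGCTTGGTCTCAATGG) was at least 24260-fold higher (limma adjusted p = 4.58e-08). The same CUST_14087 and CUST_15522 had the highest excess in the gonad, with CUST_14087 at least 5566-fold higher than in the centre (limma adjusted p = 0.00106). That p-value also reflects mostly the spread of CUST_14087 over the viscera arrays, 5.96 log2 (SD, n = 3). The count was 5872 after normexp correction, and the share of calls higher in the centre was 55.7% in the main fit, 46.0% after median centring, 47.3% after quantile normalization, 47.4% in the deposited value table and 48.7% after normexp correction.

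Mantle edge and composite viscera differed at 2202 probes, with 1349 higher in the edge and 853 higher in the viscera. CUST_12467_PI428626668 (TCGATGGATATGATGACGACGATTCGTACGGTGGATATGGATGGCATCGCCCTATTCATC) was at least 19521-fold higher in the edge (limma adjusted p = 1.74e-06). CUST_3829_PI428626668 (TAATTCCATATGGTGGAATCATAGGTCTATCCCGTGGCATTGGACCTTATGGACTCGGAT) was at least 8625-fold higher (limma adjusted p = 8.69e-05), and 2 other probes on the array had the same sequence. In the viscera, CUST_25049_PI428626668 (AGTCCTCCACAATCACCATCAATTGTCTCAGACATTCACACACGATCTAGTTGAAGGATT) was at least 14296-fold higher than in the edge (limma adjusted p = 1.51e-07), and CUST_23049_PI428626668 (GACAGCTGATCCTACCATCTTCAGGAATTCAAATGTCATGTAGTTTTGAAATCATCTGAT) at least 8025-fold (limma adjusted p = 1.03e-07). With the replicate number as a block the count rose to 3343, of which 1637 were higher in the edge and 1706 in the viscera. It was 1226 after normexp correction and 359 among probes well above background on all 12 arrays, where 151 were higher in the edge and 208 in the viscera. The viscera-higher count fell to 537 without mantle edge replicate 3 and to 562 without the arrays numbered 2.

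Mantle centre and composite viscera differed at 1958 probes, with 1190 higher in the centre and 768 higher in the viscera. CUST_11723 and CUST_66, which also led the mantle shared class, had the highest excess in the centre, and CUST_66 was at least 5089-fold higher (limma adjusted p = 2.86e-06). CUST_23049 was at least 6699-fold higher in the viscera (limma adjusted p = 1.01e-07). CUST_22329_PI428626668 (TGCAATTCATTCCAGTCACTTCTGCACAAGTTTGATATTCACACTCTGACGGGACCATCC) was at least 8873-fold higher there (limma adjusted p = 1.41e-07). With the replicate number as a block the count rose to 3229, with 1540 higher in the centre and 1689 in the viscera. It was 850 after normexp correction, 331 among probes well above background on all 12 arrays (165 and 166), and 1296 when only the arrays of these tissues were fitted (885 and 411). Single arrays moved the viscera-higher count and the majority. Without mantle centre replicate 1, 1126 were higher in the centre and 1251 in the viscera, whereas the viscera-higher count fell to 500 and 423 without mantle centre replicates 2 and 3, to 507 and 503 without viscera replicates 1 and 3, and to 492 without the arrays numbered 2.

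Gonad and composite viscera differed at 8716 probes, with 3748 higher in the gonad and 4968 higher in the viscera. Of the 883 that differed by more than 32-fold, 767 were higher in the viscera. CUST_22879_PI428626668 (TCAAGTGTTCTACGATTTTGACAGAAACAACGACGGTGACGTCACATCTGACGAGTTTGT) was at least 1645-fold higher in the viscera (limma adjusted p = 3.86e-07). CUST_22329 had a log2 fold of -12.46 ± 0.60 (SE, n = 3 per tissue, limma adjusted p = 8.42e-07), with 2 of 3 gonad arrays well above background. Which of them differed more is not settled, since CUST_22879 has only a lower bound. In the gonad, CUST_18914_PI428626668 (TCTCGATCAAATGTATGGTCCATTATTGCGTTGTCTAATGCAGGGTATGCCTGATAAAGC) was higher by a log2 fold of 7.96 ± 1.67 (SE, n = 3 per tissue, limma adjusted p = 0.00414). CUST_19036_PI428626668 (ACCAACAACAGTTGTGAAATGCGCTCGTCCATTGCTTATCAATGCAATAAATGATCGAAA) was higher by 7.91 ± 2.08 (SE, n = 3 per tissue, limma adjusted p = 0.0122), and each of these probes was well above background on 1 of 3 viscera arrays, which spread by 4.06 log2 for CUST_18914 and 4.75 for CUST_19036 (SD, n = 3). The share of calls higher in the gonad was 43.0% in the main fit, 62.5% after median centring, 52.1% after quantile normalization, 52.0% in the deposited value table and 55.2% after normexp correction, which left 4814 calls. Without the arrays numbered 2 there were 5183, with 1937 higher in the gonad and 3246 in the viscera.

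Higher in the gonad than in all other tissues were 3513 probes, led by CUST_18914 and CUST_19036. Their median level was 0.92 ± 0.19 log2 in the gonad (SD over array medians, n = 3), -2.09 ± 0.05 in the mantle edge, -2.06 ± 0.04 in the mantle centre and -1.22 ± 0.46 in the viscera. Only 13.1% of these probes were not well above background on any mantle edge array, and 4.04% on any viscera array. Higher in the viscera than in all other tissues were 323 probes, led by CUST_22329 and CUST_21937_PI428626668 (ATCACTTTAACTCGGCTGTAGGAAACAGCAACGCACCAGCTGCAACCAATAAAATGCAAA). The median level of these viscera enriched probes was 2.10 ± 0.23 log2 in the viscera, -6.75 ± 0.09 in the edge, -6.61 ± 0.11 in the centre and -5.92 ± 0.40 in the gonad (SD over array medians, n = 3). After normexp correction the classes held 2255 and 203 probes. Without the arrays numbered 2 the gonad class held 1867 probes, and among probes well above background on all 12 arrays the viscera class held 51. The gonad class also rose, to 5009 probes after median centring, 4045 after quantile normalization, 4031 in the deposited value table and 4619 with the replicate number as a block.

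Probes read in the gonad were also read on viscera arrays, and they differed between them along with the sex of the animal. A set of 335 gonad probes was at least 16-fold higher on every gonad array than on any mantle array. Of these, 180 were at least 4-fold higher on both female viscera arrays than on the male one, and 45 were at least 4-fold higher on the male array than on both female ones. At the median, the 180 probes stood at 10.6% and 25.1% of the gonad mean on the viscera arrays of females 1 and 3. On the array of male 2 they stood at no more than 1.02%, an upper limit, since only 48.3% of them were well above background there. The 45 probes stood at 17.9% of the gonad mean on the male array and at no more than 0.977% and 0.762% on the female ones, where 24.4% and 13.3% of them were well above background. Gonad array 3 lowered that mean, at a median of -0.72 log2 for the 45 probes against 2.37 and 2.22 on gonad arrays 1 and 2. Against gonad arrays 1 and 2 alone these percentages would be lower. Levels at background were raised to the lowest signal well above background for these limits. The females also differed, since 47 of the 335 probes set viscera array 3 apart from both others by at least 4-fold, 42 of them higher there. With 1 male animal, no test of the sexes was possible.

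**Figure D3:**
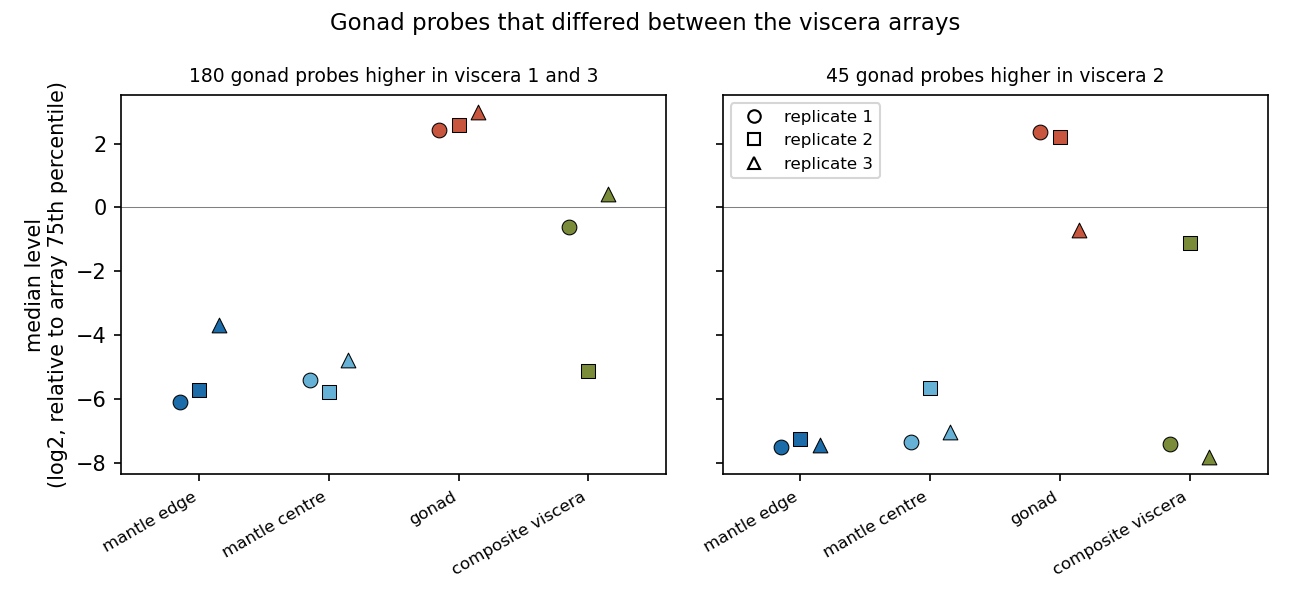
Median levels of 180 gonad probes higher on the viscera arrays of females 1 and 3 (left) and of 45 gonad probes higher on the viscera array of male 2 (right), in log2 relative to the array's 75th percentile, for each tissue and replicate number. Each symbol stands for 1 array, and both the gap between gonad and mantle and the difference between the viscera arrays were fixed by how the probes were chosen. Low medians lie near background, and 48.3% of the 180 probes were well above background on viscera array 2.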

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

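The tests in this part, those of the splits of the arrays included, were written down only after the results were seen. Outside the tested probes, 100 probes were read in mantle and viscera on all 3 arrays of animal 1 and on none of those of the other animals, with 95 such probes for animal 2 and 84 for animal 3, by at least 8-fold. Of these, 86, 92 and 76 were also well above background on the gonad array of the same number. They drew attention as a signal in data that no comparison used, since a probe was tested only if it was read on all 3 arrays of a tissue. The 24 sets of a mantle edge, a mantle centre and a viscera array that mix the animals held 0 such probes. With tested probes included there were 119, 125 and 125, and on the gonad array of that number they stood above the other gonad arrays by a median of 3.05, 3.55 and 3.08 log2, with 88.2%, 97.6% and 93.6% of them read there.

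In the opposite pattern, 226, 227 and 195 of all probes were not well above background on the 3 mantle and viscera arrays of animals 1, 2 and 3 and were read on all 6 arrays of the other animals, 648 in all against 369 seen in 1 animal. The mixed sets held 0, which argues against array noise. Of 583 such probes read on both other gonad arrays, 58.8% were read on the gonad array of that slide, where the median log2 difference was -2.94 (quartiles -4.91 and -1.12) against -5.80 (quartiles -6.77 and -4.99) in the other tissues, whose low readings were at background. Slide and animal cannot be told apart, since each slide held the arrays of 1 number. The choice of probes required a fall of at least 8-fold in the other tissues but none in gonad, so a smaller fall in gonad cannot decide between them. The lower quartile in gonad lay above the upper quartile in the other tissues on slide 1 (-4.50 against -5.07), barely so on slide 2 (-4.85 against -4.90) and not on slide 3 (-5.21 against -5.03). That requirement for each slide was set only after the pooled quartiles had been seen to lie barely apart. The probes seen in 1 animal also moved with the gonad array of that slide, which a slide effect or gonad pools of the same animals would both give. Base differences under the probe may explain part of the pattern, but of 80 similar probes read in the other animals only 53.75% were read in the animal that lacked the probe, so variants and missing transcripts both stay open.

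Mantle centre replicate 2 stood apart from the other centre arrays. For 730 mantle probes chosen without any array numbered 2, it lay below the mean of the others, with a median log2 difference of -3.35 and quartiles of -4.31 and -1.67. Dilution by other tissue would need about 90.2% of foreign RNA. At the median, 219 viscera probes stood there at no more than 0.444% of their median level in viscera 2. For 121 gonad probes this limit was 1.04% of their median level in gonad 2. More gonad probes were read there than on the other centre arrays (33.9% against 11.6% and 3.31%). Mantle edge 2 also read more of them than the other edge arrays (16.5% against 7.44% and 6.61%). These probes were chosen against the viscera arrays of females 1 and 3, which left out probes high there. On male viscera array 2, 82.6% of them were read, against 20.7% and 11.6% on the female ones. The medians of the viscera and gonad probes argue against dilution by gonad or by the viscera composite as a whole. They are no limit for single probes, and 17.8% of the viscera probes were well above background on that array. A median over probes of several organs cannot decide whether 1 organ alone was mixed in, so that was not tested. The array had the lowest median signal (85.3), 75th percentile (465) and share of probes well above background (66.4%) of all 12, but other probes as bright on the other centre arrays differed there by a median of 0.064 log2 (quartiles -0.33 and 0.38), which argues against a weak hybridization of all probes. The 730 mantle probes lay 0.58 log2 higher at the median in mantle edge replicate 2, which argues against an effect of sex or condition on the whole mantle of that animal, while the position sampled within the mantle or a state of the centre alone may remain and was not tested.

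In gonad probes, the viscera array of the only male differed from those of the females, and the arrays of the females differed less often. Sex therefore cannot be told apart from the animal. Of 335 gonad probes, 67.2% set the male viscera array apart from both others by at least 4-fold, against 4.52% of the other tested probes, while 47 of the 335 set female viscera 3 apart, a higher share than the 935 of 21648 others (4.32%), and 3 set female viscera 1 apart (0.896% against 3.62%). The slide was checked with 207 probes chosen to lie at least 4-fold lower in viscera 2, without the gonad and mantle arrays of that slide. Gonad array 2 differed from the other gonad arrays by a median of -0.26 log2 (quartiles -0.60 and -0.01) for these probes. In viscera 2 the difference was -4.41 (quartiles -6.01 and -3.23), a fall that the choice itself required. The small difference on gonad array 2 argues against the slide for these 207 probes. Probes higher in viscera 2 were not checked in this way. The ratio of viscera to gonad over the 180 probes had an interquartile range of 0.948 log2 in viscera 1 and 0.548 in viscera 3, near the 0.697 to 0.995 between gonad arrays and below the 2.17 and 1.85 of other probes read in both tissues, but not below all of the former, so expression by visceral cells stays open. Gonad RNA in the viscera samples cannot be told apart from that, since the 67.2% is the observation that raised it and no independent test was found, the labels do not list gonad among the organs pooled, and sex differences within the viscera were not tested separately.

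For each pairwise comparison the 6 arrays allow 10 splits, too few for a share under 0.05. The real splits gave 606, 11285, 2202, 11279, 1958 and 8716 probes in the order edge against centre, edge against gonad, edge against viscera, centre against gonad, centre against viscera and gonad against viscera, and the highest other splits gave 3, 0, 0, 0, 1 and 0. In each comparison 1 split, the real one, gave as many. Only 4 of the 10 splits part all pairs of numbers, as the real one does, and the highest other of these gave 0. The splits that gave 3 and 1 parted 1 pair.

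For the classes, 100 relabellings of the 12 arrays were drawn. As many probes as the real 304, 204, 863, 3513 and 323 came from 1, 3, 1, 2 and 2 relabellings, the real one included, for the edge, centre, shared, gonad and viscera classes, so each share was under 0.05. Most relabellings mix tissues that differ, so these shares speak only against no difference between any tissues. They cannot decide whether a given class arose by chance. The highest other counts were 167, 3550, 4, 3566 and 3534. Counts of that size, several times the real ones for centre and viscera, point to a structure of the samples, since tissues differ in how many probes set them apart. Among 100 relabellings within the replicate numbers, which keep the pairs parted as the real one does, 3, 2, 1, 1 and 3 gave as many, and the highest other counts were 3607, 211, 621, 0 and 3577, so those of the edge and viscera classes were again several times the real ones.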

How the results depend on the processing

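Leaving out the 4 arrays numbered 2 was chosen after seeing the data, as were counting identical sequences once and leaving out probes that set the arrays of 1 replicate number apart. The named probes kept their direction in all 1058 refits of 46 probe and comparison pairs, and 21 refits in 4 pairs, all of CUST_26107 or CUST_2331, lost the call. With normexp correction, edge against centre gave 317 probes (162 higher in the edge, 155 in the centre), edge against gonad 7358, edge against viscera 1226, centre against gonad 5872, centre against viscera 850 and gonad against viscera 4814, and the edge, shared, gonad and viscera classes held 140, 391, 2255 and 203. The cause was not tested. Among probes well above background on all 12 arrays, fewer probes are tested, and the counts were 47 for edge against centre, 359 for edge against viscera and 331 for centre against viscera, and 16, 4, 78 and 51 for the edge, centre, shared and viscera classes. The replicate block gave 3343 for edge against viscera and 3229 for centre against viscera. It also gave 786 for edge against centre, 13059 for edge against gonad, 13045 for centre against gonad and 10828 for gonad against viscera. Apart from the comparisons of mantle with viscera, the block moved no count by over 1.5 times, and it changed no call of a named probe. Fitting only the compared groups gave 1296 for centre against viscera, with fewer arrays to estimate the spread. Without the arrays numbered 2, edge against centre gave 339 (160 and 179), gonad against viscera 5183, the edge class 144 and the gonad class 1867, with fewer samples. All other alternatives kept these total counts within 1.5 times.

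Leaving out each array in turn gave 486 to 690 for edge against centre, 10480 to 11316 for edge against gonad, 1706 to 2369 for edge against viscera, 10530 to 11185 for centre against gonad, 1387 to 2377 for centre against viscera (with 1126 higher in the centre and 1251 in the viscera without mantle centre replicate 1, against 1190 and 768) and 7120 to 8779 for gonad against viscera. The edge class ranged from 233 to 317, the centre class from 192 to 217, the shared class from 708 to 923, the gonad class from 2852 to 3442 and the viscera class from 280 to 394. Scaling moved the median of all probes. For gonad against viscera it was -0.13 log2 in the main fit, 0.14 after quantile normalization and 0.39 after median centring, and for edge against gonad 0.06, -0.26 and -0.37. The higher share among calls moved with it, from 43.0% to 62.5% for gonad against viscera and from 54.0% to 42.6% for edge against gonad after median centring. Tests of gene list shifts, with their alternatives, were not run because the files name no genes. Signal over background limits folds against tissues in which a probe was not read.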

Other observations

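The tests in this part were chosen after the results were seen. Probes whose sequence reads as a glycine-rich peptide were concentrated in the mantle. A probe was counted as rich in a residue if a stop-free forward frame of its 60 bases held at least 6 of that residue. Of the 863 mantle shared probes, 26 were glycine-rich, against 19 of 21145 other tested probes (odds ratio 34.5, Fisher's exact test, two-sided, adjusted p = 2.24e-23 over 100 class and residue tests). None of the 3513 gonad enriched probes was glycine-rich (adjusted p = 0.00881). The probes they were set against include these 26, so this is not a separate result. Of the 45 glycine-rich probes, 37 were called higher in the edge than in the gonad and 32 higher in the centre than in the gonad. Examples, chosen after their values were seen, are CUST_200_PI428626668 (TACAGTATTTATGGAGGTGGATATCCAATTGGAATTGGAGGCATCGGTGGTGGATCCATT), with 9 glycines among 20 residues and a log2 fold of 14.36 between edge and gonad, where it was well above background on 2 of 3 arrays, and CUST_4147_PI428626668 (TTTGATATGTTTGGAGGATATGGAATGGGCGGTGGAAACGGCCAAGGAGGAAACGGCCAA), with 10 glycines and a log2 fold of 12.96, well above background on 1 of 3 gonad arrays.

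Glycine-rich probes were also more frequent among edge enriched probes, with 5 of 304 against 40 of 21704 others (odds ratio 9.06, adjusted p = 0.00756), and among centre enriched probes, with 4 of 204 against 41 of 21804 (odds ratio 10.6, adjusted p = 0.00881). Of the edge enriched probes, 7 were tyrosine-rich against 9 others (odds ratio 56.8, adjusted p = 4.6e-08), and 5 were asparagine-rich against 7 (odds ratio 51.8, adjusted p = 1.19e-05). Asparagine also passed among centre enriched probes (2 of 204, odds ratio 21.6, adjusted p = 0.0408). In all, 14 of the 100 tests passed, and 10 of these also passed when groups of probes that share any 20 bases were counted once. The others were alanine in the centre class (2 probes, odds ratio 108, adjusted p = 0.00769), tryptophan and valine among mantle shared probes (4 and 8 probes, odds ratios 98.5 and 3.29, adjusted p = 0.000284 and 0.0408), serine and aspartate in the gonad class (48 and 8 probes, odds ratios 1.86 and 4.22, adjusted p = 0.00769 and 0.0384), threonine, less frequent there (1 probe, odds ratio 0.119, adjusted p = 0.0494), and threonine in the viscera class (4 probes, odds ratio 6.62, adjusted p = 0.0384). With groups counted once, the calls of valine (adjusted p = 0.169), aspartate (0.205) and threonine in the gonad and viscera classes (0.0867 and 0.186) ended, tryptophan and gonad glycine stayed below 0.05 at 0.0394 and 0.0397, and methionine in the gonad class passed only then (4 groups, adjusted p = 0.0394, against 0.186 over probes). A group counted as rich if any of its probes was. No difference between classes was tested. The enrichment of glycine could come from overlapping or near-identical probes. With these groups counted once, the odds ratio in the mantle shared class was 23.6 (15 of 682 groups, adjusted p = 6.63e-12), which argues against that. Probes at positions of 1 transcript that share no 20 bases in a row were not joined, so a few transcripts with many probes stay open. That the mantle expresses several glycine-rich proteins is a hypothesis from these sequences, since the reading frames are not annotated.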
